A study of Homo sapiens with 14 samples.

How the data were processed

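Gene expression was measured in MCF10A, a non-tumorigenic human breast epithelial cell line, harvested 24 h after a single dose of 9 Gy or 23 Gy of intraoperative electron radiotherapy, and compared with untreated MCF10A cells. Each sample was a 2-colour hybridisation on an Agilent whole human genome microarray, with cRNA of irradiated cells labelled with Cy5 and cRNA of untreated cells labelled with Cy3. No array had the dyes swapped, so a dye bias of a probe and any deviation of the untreated RNA enter each ratio to untreated cells and are not part of its error. They cancel in the comparison of 23 Gy with 9 Gy where they are the same on all arrays. Of the 14 samples, 7 belong to each dose.

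Scanner files were given for 8 samples, all 7 of 9 Gy and replicate 7 of 23 Gy. Per the file headers they were made with Agilent Feature Extraction 9.5.3.1 and hold intensity, the mean brightness of each spot and the median of its local background in both channels. The authors' processed intensity values in the same files were background-subtracted, detrended and dye-normalised by Feature Extraction. Per the file headers the ratio column is the log10 of processed Cy5 over processed Cy3, with surrogate values near the background. The deposited series value table holds 45015 spots for all 14 samples in a form other than a plain ratio: the log10 ratio multiplied by 1e+09 and rounded to 3 digits. This was checked against the 8 scanner files, where 100% of the spots matched, with a relative difference of at most 0.497%. The other columns of the table have the same form. Its columns are not centred, and they were divided by the multiplier and turned to log2. How the RNA of each replicate was grown and pooled is not given in the sources used here. Names were assigned to probes by accession (23434 of 41000 gene probes), symbol (2317) or older symbol (1043), and 14206 probes stayed unmatched. The gene table used for names is of assembly 38, from which no coordinate was taken. Coordinates are those of the scanner files, whose headers name NCBI build 35 (hg17).

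The 7 files of a dose were first planned as 7 replicates. The headers and the noise of single spots, described with the data collected, showed repeat scans of 2 arrays per dose, so scans of an array were averaged before every test and n is 2 arrays per dose. This change was made after the files were seen. For 9 Gy against untreated, control spots were given no weight, the background was corrected with normexp (offset 50), ratios were normalised by loess within each scan, and spots of a probe were averaged. The offset draws the ratios of dim probes towards 0. For 23 Gy, where 1 scanner file was given, and for the comparison of the doses, the value table was used, and the 9 Gy values from the same table are given beside them. A probe was kept if it was well above background in either channel on at least 4 of the 7 scans of 9 Gy or on the 1 scan of 23 Gy. The brightest probe over the 8 scanner files stood for a gene, which gave 12484 genes. The number of arrays limits the precision, and signal per scan is given with the data collected.

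Tests used limma 3.58.1 in R 4.3.3 (data.table package, 1.17.8), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 9 Gy ratio from the scanner files was tested against 0 (residual degrees of freedom 1, prior 4.17). The value table was fitted with a mean per dose (residual degrees of freedom 2, prior 1.71), which gave 9 Gy against untreated, 23 Gy against untreated and 23 Gy against 9 Gy. Overlap between the doses was set beside the product of their shares and beside 50 simulations of unchanged doses that share a single draw of the untreated RNA. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 23 lists. These were p53 targets, mitosis and G2/M, DNA replication and G1/S, replication-dependent histones, homologous recombination and Fanconi anaemia, non-homologous end joining, BCL2 family and caspases, inflammatory cytokines and secreted senescence factors, NF-kappaB targets, interferon-stimulated genes, mesenchymal and EMT genes, basal epithelial genes, luminal epithelial genes, keratinocyte differentiation, cholesterol biosynthesis, NRF2 oxidative stress genes, unfolded protein and integrated stress response, heat shock genes, MYC and ribosome biogenesis, immediate early genes, reference housekeeping genes, fibroblast markers, and blood and endothelial cell markers. They hold 540 genes, of which HIST1H2AI, CMPK2, KRT6A, SPRR2A, AKR1C2 and HSPA1B had no matched probe. A list of hypoxia-responsive genes was added later.

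The comparisons, lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule names CDKN1A, MDM2 and GDF15, the 5 largest rises and 5 largest falls among genes past the threshold with the same sign on all files of the dose, and the members with the largest change that passed, 2 from each list that camera called and 1 from each other list. For 23 Gy against 9 Gy it goes by adjusted p and size. A gene that the rule names is not reported here. Genes given as further examples of a list were chosen after their values were seen.

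Alternatives changed the background correction, the source of the values, the normalisation within an array (median in place of loess), the scaling of the columns (centring, quantile), the filter (none, or both channels on all scans), the choice of probe, the variance model, array weights, the replicate number as a block, each replicate left out, a 2-fold threshold, and for the lists an estimated correlation, ranks and fry. Those chosen after seeing the data were each file as a replicate (also with the block), the first scan of each array alone, removal of the trend with probe GC content (loess, span 0.3), inclusion of unmatched names, each of the 4 arrays left out, and the list tests under the other scalings, backgrounds and filters. All alternatives could be run.

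The fits were tested on simulated log ratios of the arrays with 200 changed genes among 12484. Normalisation, filter and choice of probe were not part of that test. At a log2 change of 1, they recovered 100% for 9 Gy from the scanner files, 95.9% for 9 Gy from the value table, 94.4% for 23 Gy and 95.8% for 23 Gy against 9 Gy. At a log2 change of 0.5 these were 100%, 87.7%, 86.1% and 70.8%, and at a log2 change of 2 they were 100%, 100%, 100% and 96.9%. Unchanged genes called in the same order numbered 52, 20, 15 and 18. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6.

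Control spots, unmatched probes and dim probes were left out of the tests. The scanner file of 23 Gy replicate 7 was used for the filter, for the choice of probe and as a check beside the values of the table, not in a test.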

Results

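The series compares gene expression in MCF10A cells given 9 Gy or 23 Gy with that of untreated MCF10A cells, 24 h after irradiation. The labels give 7 biological replicates per dose. The headers of the 9 Gy files place replicates 1 to 3 on position 2 of a slide as its scans 1 to 3, and replicates 4 to 7 on position 3 of another slide as its scans 1 to 4. Replicate 7 of 23 Gy is scan 4 of position 4 on the second slide. The noise of single spots, measured on 202 probes printed at least 3 times (2020 spots), was shared within these sets, with a median correlation of 0.390 (range 0.244 to 0.476, 18 pairs of files). Between the sets of a dose it was 0.0448 (range -0.00837 to 0.120, 24 pairs), and between doses 0.0675 (range -0.112 to 0.209, 49 pairs). The 23 Gy files fell into the same sets of 3 and 4 by this measure, without headers for 6 of them. Values are therefore means of 2 arrays per dose, and whether the 2 arrays of a dose carry RNA from separate cultures is not known. If they do not, the SEs and adjusted p below leave out the spread between cultures. Calls against untreated cells and between the doses are then not calls over replicate cultures.

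**Figure D1:**
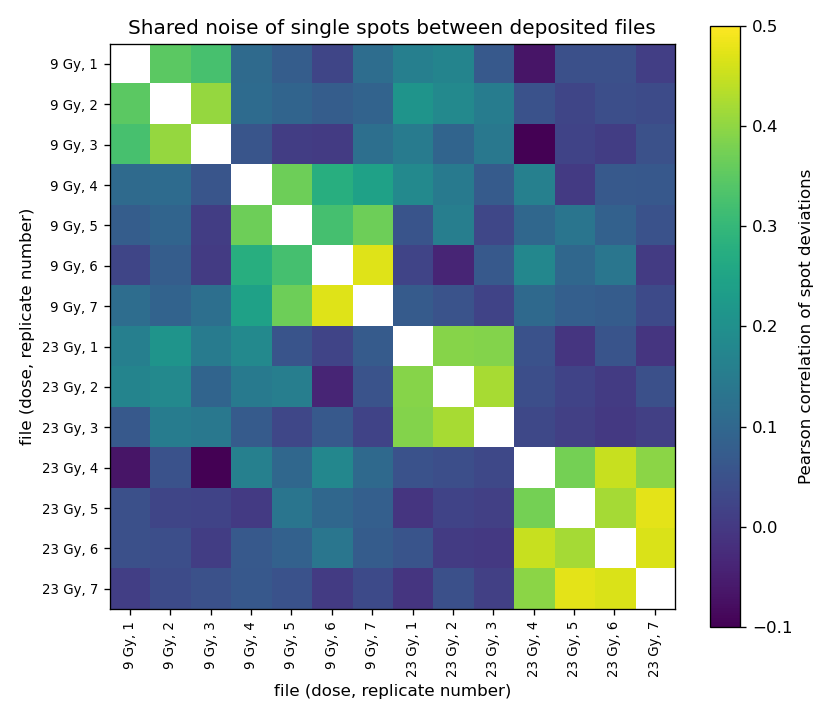
Heat map of the Pearson correlation of spot deviations, a spot's departure from the mean of its probe, between the 14 files, with both axes giving dose and replicate number. Files 1 to 3 and files 4 to 7 of each dose form blocks with a median of 0.390, against 0.0448 between the blocks of a dose.

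Signal was similar across scans. The median Cy5 signal per scan ran from 70.2 to 83.0 at 9 Gy and was 72.0 on the 23 Gy scan, and the median Cy3 signal ran from 53.3 to 62.2 and was 51.1. Cy5 was well above background at 58.1% to 64.6% of the spots of the 8 scans and Cy3 at 55.9% to 58.4%. At most 1 spot per scan was saturated, and 104 to 151 spots were marked as outliers by Feature Extraction. Across the 12484 genes, which are not independent replicates, the 2 arrays of 9 Gy had a correlation of 0.972 in the scanner values (SD of the difference 0.137) and 0.964 in the value table (SD 0.193). The 2 arrays of 23 Gy had a correlation of 0.953 in the value table (SD 0.236).

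The comparison of 9 Gy with untreated cells asks which transcripts a single dose of this size changes after 24 h. CDKN1A, the p53 target that stops the cell cycle, rose to a log2 ratio of 1.55 ± 0.0571 (SE, n = 2 arrays, adjusted p 1.0e-04), a fold of 2.94, and its probe lies on chromosome 6 from 36762684 to 36762743. GDF15, a secreted stress factor of the TGF-beta family, rose to 2.06 ± 0.0430 (adjusted p 1.3e-05, 4.18-fold; chromosome 19, 18360890 to 18360949). MDM2, which marks p53 for degradation, rose to 1.08 ± 0.177 (adjusted p 0.0061, 2.11-fold; chromosome 12, 67489279 to 67489338). Its values on the arrays were 0.69 and 1.47, and without replicate 2 it no longer passed (log2 ratio 0.89, adjusted p 0.055, range over the alternatives 9.7e-42 to 0.055). In the value table the MDM2 ratio at 9 Gy was 3.17. That source has no offset, but 19.4% to 25.4% of the gene spots per column are at exactly 0. The cause of the gap was not tested. Among 12484 genes, 3412 were higher and 3213 lower than in untreated cells, and 246 of the rises and 38 of the falls were at least 2-fold. Without replicate 2 the count fell from 6625 to 3454, and the 7 leave-one-out counts ran up to 8248.

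Scaling decided the sign of many changes at 9 Gy, and not of small ones alone. ACTB, below 0 with loess, was at 0.49 with median scaling. With each array centred on its median in place of loess, the median of all genes moved to 0.33, and 7711 genes were higher and 205 lower, so that 97.4% of the called genes were higher against 51.5% with loess. The p53 targets stayed 0.80 above that shift (33 of 34 higher, adjusted p 6.4e-12, range over the alternatives 6.4e-12 to 0.83). The replication-dependent histones lay 0.31 above it and the cholesterol genes 0.10 above it, and neither list passed (adjusted p 0.069 and 0.88).

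The largest rises at 9 Gy were those of WNT6, a secreted signalling protein, with a log2 ratio of 4.81 ± 0.0432 (SE, n = 2 arrays, adjusted p 4.1e-06, 28.1-fold), the cytochrome oxidase subunit COX6A2 (4.67), the receptor GPR153 (4.65), the transcription factor SOX3 (4.63) and the RNA-binding protein MEX3D (4.63). The probes of WNT6, GPR153, SOX3 and MEX3D have a GC content of 76.7%, 80%, 71.7% and 68.3%, and that of COX6A2 55%. Other probes gave lower ratios, down to 0.01 for WNT6 and 0.16 for MEX3D. The largest falls were those of NBPF14 (log2 ratio -1.67 ± 0.0760, adjusted p 2.2e-04), the mRNA export factor ALYREF (-1.57), the elongation factor EEF1A1 (-1.56), the importin KPNB1 (-1.45) and NBPF1 (-1.37). NBPF14 and NBPF1 belong to a family of near-identical copies, and the probes of NBPF14 ran from -1.69 to 0.90. EEF1A1 has many processed pseudogenes, and its 4 probes ran from -2.12 to -1.56. All these probes were well above background in both channels on the 7 scans.

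Camera called p53 targets, histones and cholesterol genes at 9 Gy. With an estimated correlation, which leaves camera 1 residual degree of freedom, the adjusted p of all 3 lists was 0.83, 0 lists passed and 0 had an unadjusted p under 0.05. fry called 0 lists, with 9 at an unadjusted p under 0.05. Of the 34 p53 targets, 28 rose, 1 fell and 5 did not pass at 9 Gy, and the counts were the same adjusted over the list alone. Their median log2 ratio was 0.57 (camera adjusted p 6.9e-09). The apoptosis gene BBC3 (PUMA) rose to 3.99, although on a probe of 85% GC and with its 3 probes running from 0.10 to 4.01. FDXR rose to 1.32, CYFIP2 to 1.17, DDB2 to 0.92 and TP53INP1 to 0.73, and PERP fell by 0.36. Of the 28 replication-dependent histones, 14 rose and 14 did not pass, the same as adjusted over the list alone (median 0.15, camera adjusted p 7.7e-04). H2BC5 rose to 1.43, with probes from 0.06 to 1.47, and H4C3 to 0.88. With the trend in probe GC content removed, the histone list had an adjusted p of 0.051 (range over the alternatives 4.3e-05 to 0.83). Of the 23 cholesterol biosynthesis genes, 3 rose, 15 fell and 5 did not pass (3 and 16 adjusted over the list alone; median -0.29, camera adjusted p 7.7e-04), a direction that flipped with median scaling, where their median lay 0.10 above that of all genes while the direction of camera stayed down. The sterol oxidase MSMO1 was at -1.01 (probes -1.03 to -0.17), the isomerase IDI1 at -0.77 and HMGCS1 at -0.64.

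The other 20 lists did not pass at 9 Gy (camera adjusted p 0.079 to 0.81). Among mitosis genes 14 were higher and 13 lower of 35, with the cyclin-dependent kinase subunit CKS2 at 0.59 and CDC20 at -0.53. DNA replication genes divided into 14 and 12 of 42, with the helicase subunit MCM6 at -1.19. The counts were 8 higher and 3 lower of 23 for homologous recombination and Fanconi anaemia (FANCG 0.60), 3 and 4 of 11 for non-homologous end joining (PRKDC -0.97, probes -0.98 to 0.35), and 12 and 4 of 25 for the BCL2 family and caspases (HRK 2.40, on a probe of 76.7% GC). They were 10 and 1 of 23 for cytokines (CXCL1 0.69), 8 and 3 of 18 for NF-kappaB targets (NFKBIA -0.58, but 0.42 with median scaling), and 6 and 7 of 26 for interferon-stimulated genes (BST2 -0.83). Mesenchymal genes stood at 7 and 5 of 22 (FOXC2 1.88), with a median of -0.04 and a test direction down but a mean of 0.10. Basal genes stood at 4 and 11 of 18 (TP63 -0.80, probes -0.79 to 0.04, and not called with median scaling), luminal genes at 4 and 7 of 20 (KRT8 -0.92), and keratinocyte differentiation genes at 12 and 3 of 22 (SPRR1B 1.04, list adjusted p 0.079). With median scaling, and relative to the median of all genes, basal genes turned to 0.41 above it and mitosis genes to 0.18 above it, non-homologous end joining genes lay at 0.02, and interferon-stimulated and luminal genes stayed below it at -0.25 and -0.22, with no list of these called.

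Stress and control lists were as mixed at 9 Gy. The counts were 6 higher and 8 lower of 21 for NRF2 genes (FTL -0.66, and 0.06 with median scaling, below the 0.33 of all genes), 5 and 7 of 20 for the unfolded protein and integrated stress response (HSPA5 -1.04, probes -1.06 to 0.00), and 2 and 7 of 14 for heat shock genes. HSP90AA1 was at -1.01, with probes from -1.01 to 1.51 and 0.06 as the mean over probes. MYC and ribosome biogenesis genes stood at 4 and 7 of 20 (MYC -1.31, probes -1.31 to 0.03), and immediate early genes at 6 and 9 of 19 (JUN 1.72). Housekeeping genes stood at 3 and 9 of 16, and ACTB was at -0.76 with loess but at 0.49 with median scaling, so its direction was not settled. Of the fibroblast markers 0 were higher and 2 lower of 7 (DCN -0.65, and -0.01 with median scaling, below the 0.33 of all genes). Of the blood and endothelial markers 0 were higher and 1 lower of 9 (CD14 -0.25, adjusted p 0.017, and 0.01 with median scaling, also below it). With median scaling, and relative to the median of all genes, these lists turned to lie above it: NRF2 (0.11), unfolded protein and integrated stress response (0.26), heat shock (0.20), MYC and ribosome biogenesis (0.28) and housekeeping genes (0.26). Immediate early genes lay at -0.01, and fibroblast and blood markers stayed below it at -0.15 and -0.32, and none of these lists was called. Adjusted over the list alone, 8 of these 20 lists differed: mitosis 14 and 14, homologous recombination 8 and 2, BCL2 family 12 and 5, basal 5 and 11, MYC 5 and 8, immediate early 7 and 9, housekeeping 3 and 10, and blood 0 and 0.

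The comparison of 23 Gy with untreated cells asks the same at the larger dose, from the value table. CDKN1A rose to a log2 ratio of 1.98 ± 0.0241 (SE, n = 2 arrays, adjusted p 5.4e-05, 3.94-fold) and GDF15 to 2.74 ± 0.0263 (6.68-fold). MDM2 rose to 3.53 ± 0.113 (adjusted p 2.0e-04, 11.6-fold), while the scanner file of replicate 7 with the background offset gave 0.51 for MDM2, 1.75 for CDKN1A and 2.50 for GDF15. KIF20A, a kinesin of cell division, fell by 1.92 ± 0.0311 (adjusted p 9.4e-05), and CDC20, an activator of the anaphase-promoting complex, by 1.64. Of 12484 genes, 4345 were higher and 5477 lower, and 722 of the rises and 427 of the falls were at least 2-fold. The 9 Gy columns of that source gave 4349 higher and 5319 lower, with 675 and 340 at least 2-fold.

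At 23 Gy the largest rises in the value table were those of the deubiquitinase OTUD7A (log2 ratio 6.26), ZNF575 (5.85), LINC02907 (5.83), the F-box protein FBXL17 (5.71) and the synapsin SYN1 (5.68). The probes of OTUD7A, SYN1, FBXL17 and ZNF575 have a GC content of 83.3%, 80%, 78.3% and 70%, and that of LINC02907 50%. The probes of a gene ran from -0.37 to 6.25 for OTUD7A, from -0.37 to 5.85 for ZNF575 and from -0.30 to 5.70 for FBXL17. The scan of replicate 7 gave 1.33 for OTUD7A, whose Cy3 signal was not above background there, so no fold is given for it. That scan gave 1.99 for ZNF575, 4.05 for LINC02907, 4.41 for FBXL17 and 3.57 for SYN1. The largest falls were those of the linker histone H1-5 (-3.09 ± 0.111, adjusted p 2.3e-04), MIXL1 (-2.80 ± 0.431, adjusted p 0.0063), SERTAD4 (-2.69), the homeobox protein HOPX (-2.59 ± 0.0808) and CLCA4 (-2.58). The Cy5 signal of H1-5, SERTAD4 and CLCA4 was not well above background on that scan, so these ratios rest on background estimates. There, values were -0.08 for H1-5, -0.13 for MIXL1, -0.06 for SERTAD4, -0.27 for HOPX, which was above background in both channels, and -0.03 for CLCA4.

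Probe GC content and the size of a rise went together. Probes of at least 60% GC stood for 679 of the 12484 genes (5.44%), but in the value table for 195 of the 675 rises of at least 2-fold at 9 Gy (28.9%) and 202 of the 722 at 23 Gy (28.0%). In the scanner values at 9 Gy they were 129 of 246 (52.4%). Among the falls they were 0 of 340 at 9 Gy and 1 of 427 at 23 Gy in the value table, and 0 of 38 in the scanner values. Between the doses they were 1 of 12 rises and 0 of 63 falls. The 185 genes on probes of at least 70% GC had a median log2 ratio of 2.09 at 9 Gy, 2.16 at 23 Gy and 0.18 between the doses in the value table, and 0.93 at 9 Gy in the scanner values, where the offset draws dim probes towards 0.

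**Figure D2:**
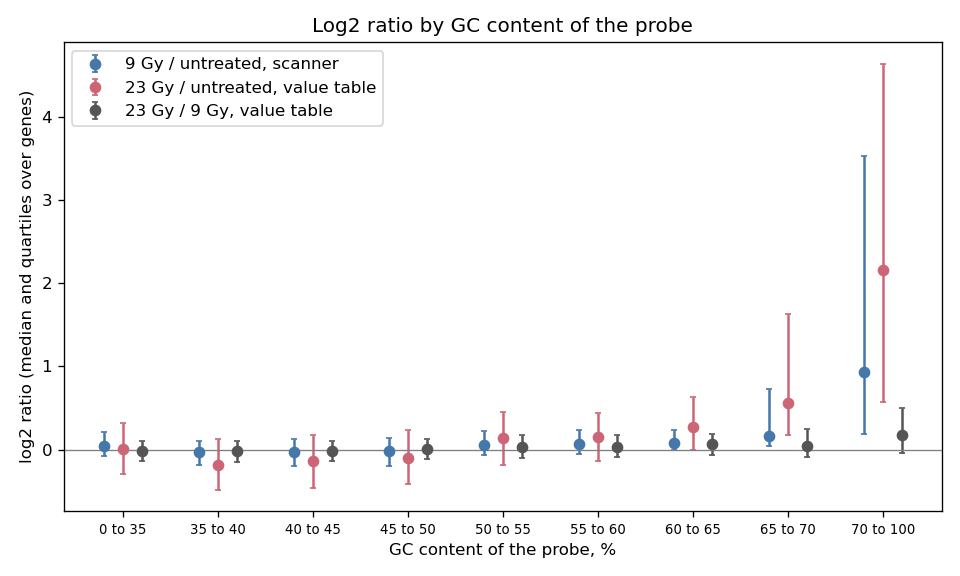
Median log2 ratio with quartiles over genes (y axis) by GC content of the probe in percent (x axis), for 9 Gy over untreated (scanner), 23 Gy over untreated and 23 Gy over 9 Gy (value table). In the bin of 70% and more the medians are 0.93, 2.16 and 0.18, and the 9 Gy median in the value table, not drawn, is 2.09.

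Camera called 7 of the 23 lists at 23 Gy. With an estimated correlation, which leaves 2 residual degrees of freedom, the adjusted p was 0.40 for p53 targets, 0.67 for cytokines and 0.61 for the other 5 lists. That setting called 0 lists, with 1 at an unadjusted p under 0.05, and fry called 19. Among p53 targets 32 rose and 2 fell of 34 (median log2 ratio 0.94, camera adjusted p 1.5e-09). FDXR was at 1.63 and TP53INP1 at 1.55, and the falls were those of PERP (-0.40) and CCNG1 (-0.24). BBC3 was at 4.89 on its GC-rich probe, with a range over the alternatives of 2.27 to 5.27. MDM2 was at 3.53, but far lower on the scan of replicate 7, as given above. All 35 mitosis genes fell (median -0.98, adjusted p 1.7e-09), among them KIF20A, CDC20, MKI67 (-1.43) and CCNB1 (-1.09). Among histones 17 rose and 2 fell of 28 (17 and 1 adjusted over the list alone; median 0.20, adjusted p 0.0036), with H2BC5 at 1.77 and H1-1 at -1.22. NF-kappaB targets gave 12 rises and 3 falls of 18 (median 0.43, adjusted p 0.024), with the superoxide dismutase SOD2 at 0.81 and the adhesion protein ICAM1 at 0.78. Cytokines and secreted factors gave 14 rises and 5 falls of 23 (median 0.43, camera adjusted p 0.028), with the cytokine LIF at 1.91 and CCL20 at 1.11. SERPINB2 was at -1.95, but its Cy5 signal was not above background on any of the 8 scans. That size therefore rests on a background estimate. MYC and ribosome biogenesis genes gave 2 rises and 16 falls of 20 (median -0.25, adjusted p 0.024), with MYC at -1.25 (probes -1.25 to 0.52) and WDR43 at -0.81. Cholesterol biosynthesis genes gave 3 rises and 17 falls of 23 (median -0.26, adjusted p 0.037), with MSMO1 at -0.86. Adjusted over the list alone, the counts of the other 6 lists were the same.

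Several of these calls moved with a single choice. Without the second 23 Gy array, camera no longer called MYC and ribosome biogenesis, cytokines or cholesterol. The medians of these lists stayed about as large, at -0.23, 0.40 and -0.25. Their ranges over the alternatives of camera were 0.0047 to 0.61, 0.0034 to 0.67 and 0.0088 to 0.61. With the GC trend removed, the histone median fell to 0.046 (camera adjusted p 0.41, range 0.00063 to 0.61). NF-kappaB targets then had a median of 0.31 (camera adjusted p 0.068, range 0.0088 to 0.61). Cholesterol genes kept a median of -0.27 (camera adjusted p 0.068).

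The other 16 lists did not pass at 23 Gy (camera adjusted p 0.14 to 0.97). The counts were 13 higher and 22 lower of 42 for DNA replication (CCNE2 -1.57, with Cy5 not above background on any scan; 14 and 22 adjusted over the list alone), 11 and 8 of 23 for homologous recombination (PALB2 -0.92; 12 and 9 over the list alone) and 3 and 8 of 11 for non-homologous end joining. PRKDC was at -1.08, with probes from -1.08 to 1.63 and 0.27 as their mean. The BCL2 family and caspases stood at 12 and 9 of 25 (HRK 2.96), interferon-stimulated genes at 8 and 12 of 26 (IFI44L -1.58), mesenchymal genes at 7 and 10 of 22 (FOXC2 2.03), with a median of -0.01 and a mean of 0.02, basal genes at 6 and 12 of 18 (TP63 -0.88, probes -0.89 to 0.71), luminal genes at 6 and 11 of 20 (ELF3 -1.57) and keratinocyte genes at 7 and 14 of 22. The cornified envelope gene LCE3D was at 2.64, with Cy3 not above background on any scan. The sizes given for CCNE2 and LCE3D therefore rest on background estimates. NRF2 genes stood at 7 and 10 of 21 (ABCC2 1.05), heat shock genes at 2 and 10 of 14 (HSP90AA1 -1.10, probes -1.10 to 1.01) and housekeeping genes at 5 and 10 of 16 (POLR2A 0.88). For the unfolded protein and integrated stress response they were 8 and 9 of 20 (HSPA5 -1.27), with a median of 0.02 and a test direction up but a mean of -0.10. For immediate early genes they were 7 and 9 of 19 (JUN 1.87), with a median of 0.01 and a test direction up but a mean of -0.03. Fibroblast markers stood at 3 and 2 of 7 (PDGFRA 0.63) and blood and endothelial markers at 2 and 3 of 9 (KDR 1.27, with Cy3 above background on 2 of the 7 scans of 9 Gy).

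In the value table at 9 Gy, camera called p53 targets (28 rose and 2 fell of 34, median 0.70, adjusted p 1.8e-07), histones (15 and 2 of 28, adjusted p 0.010, 0.60 with the GC trend removed, range 0.0017 to 0.77) and cholesterol genes (3 and 17 of 23, adjusted p 0.016). With an estimated correlation their adjusted p was 0.50, 0.77 and 0.77, 0 lists passed, 1 had an unadjusted p under 0.05, and fry called 19. The other 20 lists had an adjusted p of 0.066 to 0.89.

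**Figure D3:**
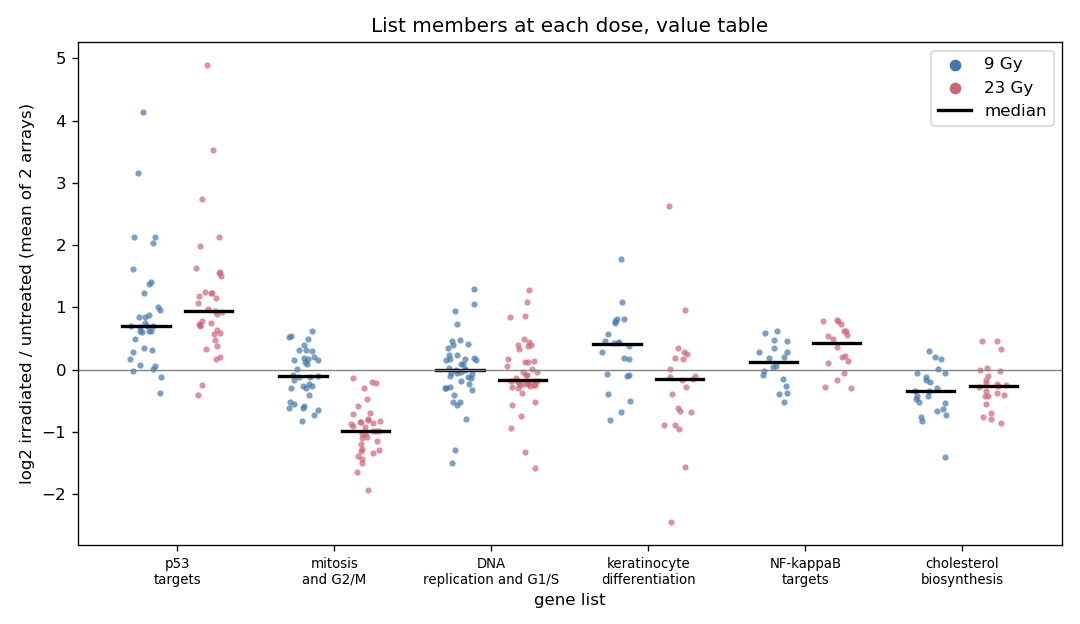
Log2 ratio of irradiated over untreated cells (y axis, value table, mean of 2 arrays) for each member of 6 gene lists (x axis) at 9 Gy (blue) and 23 Gy (red), with black bars at the medians. The p53 targets move from a median of 0.70 to 0.94 and the mitosis genes from -0.10 to -0.98, while the median of the cholesterol genes lies below 0 at both doses in this table, a direction that flips at 9 Gy in the scanner values with median scaling (0.10 above the median of all genes).

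The direct comparison of 23 Gy with 9 Gy asks which changes depend on the dose. UBE2C, the ubiquitin-conjugating enzyme of mitotic exit, was lower at 23 Gy by a log2 difference of -1.31 ± 0.0373 (SE, n = 2 arrays per dose, adjusted p 0.0095), and the mitotic kinase PLK1 by -1.29 ± 0.0321. SPRR3, a cornified envelope protein, differed by -1.83 ± 0.0341 and the carbonic anhydrase CA9 was lower 4.00-fold (SE of the log2 difference 0.0363, adjusted p 0.0095 for both). Of 12484 genes, 1281 were higher and 1233 lower at 23 Gy, and 12 and 63 of these by at least 2-fold. These counts depended on having 2 arrays in both groups. Without either 9 Gy array limma called 0 genes (3652 and 3644 at an unadjusted p under 0.05), without the first 23 Gy array 15 (3768), and without the second 0 (3678). The lone array of a dose is then assumed to vary like those of the other dose. Per the headers the second 9 Gy array shares a slide with the 23 Gy array of replicate 7. With the first and second arrays of the doses paired by a replicate block, limma called 0 genes (4394 at an unadjusted p under 0.05, smallest adjusted p 0.064), with 1 residual degree of freedom.

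Larger at 23 Gy were the riboflavin transporter SLC52A1 (1.29 ± 0.106, adjusted p 0.017), the creatine kinase CKB (1.18, probes -0.32 to 1.19), ASPA (1.15), HS2ST1 (1.12, probes -0.28 to 1.13) and ST8SIA1 (1.10). Among the 5 largest differences downwards, CA9, SPRR3 and HOPX (-1.80) were on probes above background in both channels on all 8 scans. For HOPX, however, the 23 Gy scan with the offset gave a far smaller fall against untreated cells than the value table. KRT24 and PXDNL were also called lower, but KRT24 was above background in Cy3 on none of the scans and neither was above background in either channel on the 23 Gy scan, so no fold is given for them. KRT24 passed in 16 of 30 alternatives. In all of these genes both array sets moved the same way, and without the filter SLC52A1, ASPA, HS2ST1, ST8SIA1 and KRT24 no longer passed.

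Camera called 5 of the 23 lists between the doses. An estimated correlation gave an adjusted p of 0.29 for mitosis and for p53, 0.43 for keratinocyte, 0.46 for NF-kappaB and 0.49 for MYC. That setting called 0 lists, with 2 at an unadjusted p under 0.05, and fry called 12. Of 35 mitosis genes, 34 were lower at 23 Gy and 1 did not pass (35 lower adjusted over the list alone), with a median log2 difference of -0.83 (camera adjusted p 5.4e-25) and set medians of -0.86 and -0.83. HMMR differed by -1.22, CCNB1 by -0.99 and CDK1 by -0.80, and MKI67, at -0.60, was the gene that did not pass. Keratinocyte differentiation genes were lower in 17 of 22 and higher in 0 (17 and 1 adjusted over the list alone; median -0.56, adjusted p 2.1e-07), with SPRR3, the calmodulin-like CALML5 (-1.77), KRT4 (-1.27) and PI3 (-1.15). Among p53 targets 18 were higher and 1 lower of 34 (23 and 2 over the list alone, median 0.25, camera adjusted p 6.8e-07), with BBC3 at 0.75, TP53INP1 at 0.70 and GDF15 at 0.61. BBC3 was at 0.34 with quantile scaling (limma adjusted p 0.14), and without the filter it no longer passed. EDA2R was at -0.80 and passed in 16 of 30 alternatives. Its Cy3 signal was not above background on any scan, so that size rests on background estimates. NF-kappaB targets were higher in 10 of 18 and lower in 0 (11 and 0 over the list alone; median 0.26, adjusted p 5.0e-04), with IRF1 at 0.61, BIRC3 at 0.45 and LTB at 0.60, which passed in 14 of 31 alternatives. MYC and ribosome biogenesis genes were lower in 5 of 20 and higher in 0 (11 and 0 over the list alone; median -0.18, adjusted p 2.7e-04), with the nucleolar proteins NOP58 at -0.39 and NOP16 at -0.35.

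The other 18 lists did not pass between the doses (camera adjusted p 0.051 to 1.0). Cholesterol genes were higher at 23 Gy in 8 of 23 and lower in 0 (11 and 0 over the list alone, MSMO1 0.54, adjusted p 0.051), cytokines higher in 10 and lower in 4 of 23 (11 and 5 over the list alone, PLAU 0.56, adjusted p 0.056), and luminal genes higher in 1 and lower in 4 of 20 (1 and 5 over the list alone, AGR2 -0.53, passed in 15 of 30 alternatives, list adjusted p 0.092). With the GC trend removed these had an adjusted p of 0.036, 0.036 and 0.049, with ranges over the alternatives of camera of 0.013 to 0.55, 0.0073 to 0.55 and 0.049 to 0.55. DNA replication genes were lower in 3 and higher in 0 of 42 (1 and 0 over the list alone, E2F2 -0.43, probes -0.42 to 0.11), with a median of -0.06 (quartiles -0.13 and 0.02). Higher and lower counts were 4 and 5 of 28 for histones (6 and 5 over the list alone, H4C3 -0.64), with a median of 0.04 and a mean of -0.00. They were 0 and 1 of 23 for homologous recombination (0 and 0 over the list alone, BLM -0.37), 0 and 2 of 11 for non-homologous end joining (0 and 1 over the list alone, XRCC4 -0.33) and 4 and 2 of 25 for the BCL2 family and caspases (CASP8 0.89, probes -0.47 to 0.90).

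Interferon-stimulated genes stood at 4 and 3 of 26 between the doses (8 and 4 over the list alone), with a median of -0.02 and a test direction up. Their largest listed difference was that of MX2, whose Cy5 signal was not above background at either dose. That rank thus rests on background estimates, and no fold is given. Mesenchymal genes stood at 4 and 1 of 22 (7 and 3 over the list alone, CCN2 0.52, median 0.03, mean -0.01), basal genes at 3 and 1 of 18 (KRT6B -1.14, median 0.02, mean -0.01) and NRF2 genes at 3 and 1 of 21 (ABCC2 0.58). The unfolded protein and integrated stress response stood at 5 and 5 of 20 (HYOU1 0.43), heat shock genes at 1 and 2 of 14 (HSPE1 -0.38) and immediate early genes at 4 and 3 of 19 (5 and 4 over the list alone, DUSP5 0.37, median -0.00, mean 0.01). Housekeeping genes stood at 2 and 3 of 16 (HPRT1 -0.23, median and mean 0.02, test direction down), fibroblast markers at 1 and 0 of 7 (3 and 0 over the list alone, FBLN1 0.22) and blood and endothelial markers at 1 and 0 of 9 (0 and 0 over the list alone, KDR 0.39, passed in 12 of 30 alternatives, median -0.04, mean 0.08). Counts adjusted over the list alone were the same where none is given.

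Overlap between the doses was large in the value table. Of the called genes, 3659 were higher at both doses and 4647 lower at both, against 1514 and 2334 from the product of their shares, and 289 were called in opposite directions. Across genes, which are not independent replicates, the log2 ratios of the doses had a Pearson r of 0.934, a Spearman rho of 0.896 and a covariance of 0.501. In 50 simulations of unchanged doses that share the untreated RNA, the means were 1.14 and 1.28 shared genes, an r of 0.672 and a covariance of 0.0137. With the GC trend removed, r was 0.922 and the covariance 0.413. Every array carries untreated RNA in Cy3, which cannot be split between the doses, so what a shared control or a shared dye bias adds to the overlap was not separated from a shared response. CDKN1A, GDF15 and MDM2 were among the genes higher at both doses, and KPNB1, MYC and HSPA5 among those lower at both.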

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

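Of the tests in this part, those of the mitotic genes and of the spike-ins were chosen after the results were seen. The genes below are those of the named genes that were called in opposite directions at the 2 doses in the value table and whose difference between the doses was itself called by limma. Among all genes 286 were of this kind, 173 of them higher at 9 Gy and lower at 23 Gy and 113 the reverse, with 15 mitosis genes and 9 keratinocyte differentiation genes among the 173. These counts rest on the fit without the replicate block, since with it limma called 0 genes between the doses (4394 at an unadjusted p under 0.05, smallest adjusted p 0.064). No file stood apart from the others of its dose in the 10 technical measures tested. An array that differed would move all its scans together, which a test for a single file apart cannot show. Most of these were scanner measures of the 9 Gy files alone. The median ratio of a file was 0 throughout and could single out none. For 23 Gy, only the share of spots at 0 could do so.

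CKS2, a subunit of cyclin-dependent kinases, had a log2 ratio of 0.62 at 9 Gy and -0.13 at 23 Gy, a difference of -0.75 (SE 0.0337, n = 2 arrays per dose). UBE2C went from 0.50 to -0.81 (difference -1.31) and PLK1 from 0.30 to -0.99 (difference -1.29). The cornified envelope protein SPRR3 went from 0.28 to -1.55 (difference -1.83) and the keratin KRT6B from 0.29 to -0.85 (difference -1.14). The ligase partner XRCC4 went from 0.15 to -0.17 (difference -0.33), and the nucleolar proteins NOP58 from 0.30 to -0.10 (difference -0.39) and NOP16 from 0.10 to -0.25 (difference -0.35). In the other direction, the transcription factor IRF1 went from -0.38 to 0.23 (difference 0.61) and the chaperone HYOU1 from -0.14 to 0.29 (difference 0.43). MX2 met the same criterion with a listed difference of -1.32, but its Cy5 signal was not above background at either dose, so that value is not read as a fold. Each difference had the same sign in both array sets.

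The mitotic genes as a set were lower at 23 Gy than at 9 Gy by camera at a preset correlation (adjusted p 5.4e-25), but not with an estimated correlation (adjusted p 0.29). A trend with probe GC content as the whole cause is argued against by the median of the list with that trend removed (-0.84), and a single array set as the source by the median in the set where the difference was smaller (-0.83). A fall of all proliferation transcripts alike is argued against by the DNA replication list, whose median was -0.061 (quartiles -0.13 and 0.02). What stays open is an effect of the dose, as a hypothesis, or a difference between single cultures that has nothing to do with dose, because it is not known whether the arrays of a dose hold separately labelled RNA. The spike-in intercepts of the 9 Gy arrays lay closer together (0.269 and 0.271 in log10, 0.00183 apart) than to that of the 23 Gy array of replicate 7 (0.247), but that is a single array to judge by.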

How the results depend on the processing

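Of the tests in this part, those chosen after seeing the data were the files as replicates, the first scan alone, the removal of the GC trend, unmatched names, each array left out, and the list tests under other scalings, backgrounds and filters. Over all alternatives, 1079 of 1219 list results kept their direction and side of the threshold, 33 lost and 53 gained a call, 1 reversed and 53 values moved. For single genes 3003 of 3307 results kept both, 262 lost the call, 6 reversed and 36 moved. Nearly all of the lost calls were between the doses. Leaving out files of a dose cannot change the other dose's ratio to untreated cells, which adds to the results that kept both. Signal over background limits the dim probes, whose ratios the offset draws towards 0. All alternatives were run. Except where said below, the cause was not tested.

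With a 2-fold threshold the counts were 284 of 6625 at 9 Gy, 1149 of 9822 at 23 Gy, 1015 of 9668 at 9 Gy in the value table, 75 of 2514 between the doses and 781 of 8306 shared, as fewer genes reach it. With each of the 7 files as a replicate, they were 9954 at 9 Gy and 7475 between the doses (7384 with the block), as scans of an array share its noise. Between the doses, no filter gave 961 and the first scan alone 1601. Leaving out single replicates or arrays gave 3454 (without replicate 2) to 8248 genes at 9 Gy and 0 to 2520 between the doses. Without either 9 Gy array limma called 0 (3652 and 3644 at an unadjusted p under 0.05), without the first 23 Gy array 15, and without the second 0 (3678). These fits had 3 arrays, and the lone array of a dose is assumed to vary like those of the other. With the replicate number as a block, limma called 0 genes between the doses (4394 at an unadjusted p under 0.05, smallest adjusted p 0.064). Gene values of like-numbered files, as deviations from the dose mean, correlated at 0.0426 to 0.101 between the doses. Of the 7 files of 9 Gy, 6 correlated best with their own number, a hint of pairing. Not every correlation was over 0.1 and the labels do not say that like numbers are paired, so they were not taken to pair the samples. Per the headers the second 9 Gy array shares a slide with the 23 Gy array of replicate 7, and replicate 7 of each dose is scan 4 of that slide. Whether the first arrays share a slide is not known. Single-spot noise of the first sets of the 2 doses correlated at 0.067 to 0.209. Between the first 9 Gy set and the second 23 Gy set it was -0.112 to 0.051, another hint of pairing. The second sets gave 0.0022 to 0.178. The second 9 Gy set with the first 23 Gy set gave -0.038 to 0.182, so this measure cannot decide it. The limma calls of single genes between the doses therefore hold only if the arrays are not paired. The lists that camera called between the doses each passed in 12 of 13 settings, the block among them. They did not pass with an estimated correlation.

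Camera called 3 lists at 9 Gy, 7 at 23 Gy, 3 at 9 Gy in the value table and 5 between the doses. An estimated correlation called 0 in each (0, 1, 1 and 2 at an unadjusted p under 0.05), as it rests on 1 or 2 residual degrees of freedom, with smallest adjusted p of 0.83, 0.40, 0.50 and 0.29. fry called 0 (9 at an unadjusted p under 0.05), 19, 19 and 12. At 9 Gy no filter called 5 lists and median scaling 1. With the GC trend removed camera called 4 at 23 Gy and 8 between the doses. Leaving out arrays gave 4 (without the second 23 Gy array) to 7 lists at 23 Gy. The unfolded protein and integrated stress response at 23 Gy, with a median of 0.019, was called downwards by fry. Between the doses, the calls of 37 named genes ended with the block and without any of the arrays but the first of 23 Gy, whose omission ended 34. No filter ended those of SLC52A1, ASPA, HS2ST1, ST8SIA1, KRT24, EDA2R, BBC3, BLM, IRF1, LTB, AGR2, DUSP5, HPRT1 and KDR, the mean over probes those of E2F2, CASP8, FBLN1, KRT24, LTB and KDR, and quantile scaling those of BBC3, LTB and KDR. The first scan alone ended those of KRT24, EDA2R, LTB, MX2, AGR2 and KDR, unmatched names those of KRT24, LTB, AGR2, DUSP5 and KDR, trend and robust that of KDR, and each file as a replicate, with or without the block, that of EDA2R. Leaving out single scans ended calls of KRT24, EDA2R, LTB, MX2, AGR2, DUSP5 and KDR.

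Median scaling in place of loess turned the sign of NFKBIA (0.42), ACTB (0.49), FTL (0.062) and CD14 (0.011) at 9 Gy, of which FTL and CD14 stayed below the median of all genes, and ended the calls of TP63 (-0.03), IDI1 (-0.05), HSP90AA1 (-0.17) and DCN (-0.01), while the median of all genes moved to 0.33, and the cause was not tested. The mean over probes reversed HSP90AA1 at 9 Gy (0.058) and PRKDC at 23 Gy (0.27), whose probes differ in sign, and ended the call of TP63 at 23 Gy (-0.10). Without replicate 2, CD14 (-0.21) and MDM2 (0.89) no longer passed at 9 Gy.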

Other observations

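Of the tests in this part, those of the 7 files per dose, the control sets of other probes and the list of hypoxia-responsive genes were chosen after results had been seen. That list was prompted by the difference in CA9, a target of hypoxia-inducible factor. The genes CA9, EGLN3, VEGFA and TMEM45A were left out of it because their values had been seen. Of the other 22 genes, 2 were higher and 5 lower at 23 Gy than at 9 Gy (3 and 8 adjusted over the list alone), and 13 had a negative difference. The median was -0.07, and camera gave an adjusted p of 0.30 (0.69 with an estimated correlation). A fall of these genes as a set was not shown. The 5 lower genes, named after their values were seen, were LOX (-0.58), SLC2A1 (-0.46), PDK1 (-0.30), ANKRD37 (-0.27) and PGK1 (-0.16). Against untreated cells 3 were higher and 15 lower at 9 Gy (adjusted p 0.11) and 3 and 13 at 23 Gy (2 and 13 over the list alone, adjusted p 0.051).

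The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 2514 genes and the highest of the others 0, which makes 1 split with as many.

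For the 7 files of 9 Gy, labelled as biological replicates, separate arrays are argued against by the noise of single spots. Within the sets that the headers give it correlated at 0.244 to 0.470, and between them at 0.0054 to 0.120. Over both doses the median within sets exceeded that between the sets of a dose by 0.345. The sets were formed from this same noise, so that excess is partly built in. For 23 Gy no header gives the sets independently. Repeat scans of 2 arrays meet the value they need, a median correlation of 0.390 within sets, and the headers of the 9 Gy files give the scan numbers. Whether 1 labelled sample was put on both arrays of a dose cannot be told apart from separate labelling by the spike-ins. Their mean intercepts (log10) on the 9 Gy arrays were 0.269 and 0.271, a difference of 0.00183, against 0.247 on the 23 Gy array of replicate 7, which carries other Cy5 RNA. A single array known to be labelled apart, and of another dose, does not give the spread between separate labellings, which keeps this open.

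Rises of at least 2-fold at 23 Gy on probes of at least 60% GC might come from probe GC content on these arrays or from higher transcript levels. Other probes of the same genes with a GC content under 55% (52 probes of 39 genes) had a median log2 ratio of 0.19 and an upper quartile of 0.40, against a median of 3.96 for the GC-rich probes. Those values were set in advance as speaking for the probes. A control added later put that bound in doubt. There, 170 other probes of genes rising on probes under 55% GC had a median of 0.28 and an upper quartile of 0.92, against 1.33. For genes that fell on probes under 55% GC, 112 other probes had a median of -0.67, against -1.15. Second probes thus followed falls more closely than rises, and often missed a rise on any probe. The explanations cannot be told apart, as this series holds no other platform.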
